A study of Nostoc punctiforme PCC 73102 with 5 samples.

How the data were processed

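Hormogonium development of Nostoc punctiforme was followed by RNA sequencing at 0, 1, 6, 12 and 18 h after induction, with 1 library at each time. Per the labels' protocols, cultures grown with 30 mM fructose and 2.5 mM NH4Cl in a 4-fold dilution of the AA medium were harvested at 1000 g for 5 min, washed 3 times and brought to 2 to 3 µg chlorophyll a per ml in fresh medium with the inducing factor. Total RNA was depleted of ribosomal RNA with Ribo-Zero, and libraries of 200 bp were sequenced together on a HiSeq 2000, per the labels' protocols. Each library was assigned to its time from its own label. No untreated culture washed and held for the same times was analysed here.

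The deposited table had 7099 entries on the chromosome and the plasmids pNPUN01 to pNPUN05, with start, end, strand and product for each. The authors deposited estimated counts of reads, written as whole numbers. Dividing the normalized values by their factor gave numbers that exceeded the written counts by 0 to 1, so the deposited expected counts appear truncated. The authors deposited 3 further scores per library, headed normalized counts, RPKM and expression per the file headers and rounded to whole numbers by the authors; these were examined but not used for the comparisons. The authors deposited p-values and q-values for each pair of libraries, without naming the test. The aligner, the counting program, their versions, the treatment of reads with several matches and the use of strand were not given in the sources used here. Values of near-identical copies and of overlapping or antisense genes are therefore uncertain. Coordinates are those of the deposited table, counted from 1. Gene names came from the deposited table and from a RefSeq gene table of assembly ASM2002v1, in which 6578 of 6693 genes were matched by locus tag.

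The deposited counts were used without further rounding. Ribosomal and transfer RNA entries (104) were left out of all comparisons. A further 302 predicted RNAs, of which 79 were named as antisense to genes, were left out because they name no gene, a choice made after the table was seen. Predicted RNAs held 5.07% of the counts at 0 h, 3.21% at 1 h, 3.48% at 6 h, 4.55% at 12 h and 4.27% at 18 h. Scaling used the trimmed mean of M values (TMM) from edgeR 4.0.16 (limma 3.58.1, R 4.3.3), with factors of 0.651 at 0 h, 1.21 at 1 h, 1.25 at 6 h, 1.10 at 12 h and 0.924 at 18 h. Log2 ratios were taken of scaled counts plus a pseudocount of 1. Genes with a mean of at least 50 counts over the 5 libraries were compared, which kept 6169 and left out 524. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

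With 1 library per time there was no spread between replicates, so no test was run and no p-value was computed. Genes were counted as higher or lower when their scaled counts differed by at least 4-fold, and counts at 2-fold are given as an alternative. Each log2 ratio has a 95% interval from the exact conditional binomial (Clopper-Pearson) limits of the pair of counts. Shares of counts have Wilson intervals. These intervals cover counting error only. They may be too narrow even for that, because PCR reads without molecular identifiers are not independent molecules.

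Gene lists were defined by product, symbol or locus tag before the data were examined, as were the comparisons, the count minimum, the thresholds, the naming rule and the alternatives not said below to be added. There were 29 lists, of which 28 had at least 5 members above the count minimum and were scored. The members of the hps, hmp and ptx loci were written from memory of their locus tags. Some search patterns were narrowed after members were seen but before list values were computed. This removed 10 genes of proteins with a PilT domain from the pilus list, among other mismatches. Each list's median was placed among the medians of 10000 random lists of equal size, drawn within 10 bins of mean expression with seed 11. The percentile is a description of these libraries, and a list outside the central 95% is called above or below the random range. Lists of adjacent genes can fall outside more readily than random lists, whose members are mostly not neighbours. In comparisons with 0 h, the median and mean of a list differed in sign for DNA replication and cell division at 6 h (median −0.04, mean 0.10), nitrogen assimilation at 1 h (−0.15 and 0.03) and sugar catabolism and glycogen at 6 h (0.09 and −0.01). They also differed for the hrm locus at 12 h (0.19 and −0.04), a list added after the values were seen. A second added list joined 7 genes of pil loci.

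Named genes were, for each comparison with 0 h, the 10 with the largest and the 10 with the smallest log2 ratio among those at least 4-fold apart whose product was informative. Within each list they were the members with the largest, smallest and median value at the time of the list's largest absolute median, and up to 2 further members of high mean count. Sigma factor genes and a few single genes, such as pilA, hetR, ftsZ, ntcA, gvpA, psbA, cpcA, rbcL, groEL and dnaK, were named in advance. A gene that this rule takes is not reported here. Among the overall 10 highest and 10 lowest genes, hypothetical genes numbered 3 and 6 at 1 h, 4 and 6 at 6 h, 3 and 2 at 12 h and 3 and 4 at 18 h.

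The calculations were tested on simulated counts for 18 h against 0 h with 6171 genes above the minimum. Of genes simulated as 8-fold different, 50 of 50 were counted as higher and 50 of 50 as lower. At 2-fold, 0 of 50 were counted in each direction, as were 0 of 5969 unchanged genes. The interval covered the simulated value for 95.2% of unchanged genes. Of 200 random lists in the simulated data, 12 (6%) fell outside the central 95%. For the comparison of neighbouring genes, tested for 1 h against 0 h with 6169 genes, independent simulated counts gave a difference of correlations of 0.049 (−0.036 to 0.137).

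Alternatives were median-of-ratios, upper-quartile and total-count scaling, pseudocounts of 0.1 and 10, no count minimum or a minimum of 200, ribosomal and transfer RNA kept, a 2-fold threshold, a 4-fold threshold beyond the counting interval, and list means. Alternatives added after the data were seen were predicted RNAs kept, counts thinned to the shallowest library, the 1 h library as reference, total counts without psaA and psaB, the pair of added lists, and antisense RNAs averaged by family. A family joined pairs that shared an antisense RNA or a gene, or whose antisense RNAs had log2 ratios within 0.1 of another member at all 4 times.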

Results

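RNA was sequenced from the filamentous cyanobacterium Nostoc punctiforme (ATCC 29133, also held as PCC 73102) during the development of hormogonia, the short motile filaments that vegetative filaments form for a limited time. Filaments grown with 30 mM fructose and 2.5 mM NH4Cl were washed 3 times and moved to fresh medium that held hormogonium inducing factor from the hornwort Anthoceros punctatus, a plant host of this organism. Total RNA depleted of ribosomal RNA was sequenced at 0, 1, 6, 12 and 18 h after induction, with 1 library at each time. There were no replicates, so no difference reported here has a replicate check, and the intervals cover counting error only. Deposited read counts summed to 39656594 at 0 h, 52701727 at 1 h, 35883266 at 6 h, 31562107 at 12 h and 32731849 at 18 h. At this depth, the 95% counting interval of the log2 ratio to 0 h had a median width per gene of 0.28 at 1 h, 0.30 at 6 h, 0.32 at 12 h and 0.33 at 18 h.

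The photosystem I reaction centre genes psaA and psaB (chromosome, 4817170 to 4819428, and chromosome, 4819549 to 4821774) together held 29.3% of the counts of all genes at 0 h, 11.4% at 1 h, 9.04% at 6 h, 4.24% at 12 h and 3.16% at 18 h. Ribosomal RNA left after depletion was 1.92% of all counts at 0 h, 0.617% at 1 h, 0.297% at 6 h, 0.242% at 12 h and 0.231% at 18 h. The widest 95% Wilson interval of these shares spanned 0.029 percentage points. Because a few genes held so many counts at 0 h, the scaling between libraries matters for every comparison with 0 h. Trimmed-mean (TMM) scaling left the median log2 ratio of all genes near 0, and scaling to the total count raised that median by 0.90 at 1 h, 0.93 at 6 h, 0.75 at 12 h and 0.50 at 18 h. Small negative log2 values under trimmed-mean scaling therefore turned positive under total-count scaling. Random gene lists moved with this shift, so all 28 scored lists kept their place above, within or below the random range at every time under each of the other scalings.

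The comparison of 1 h with 0 h asks which genes differed soon after induction. Genes of the hrm locus, which has been linked to the control of hormogonium formation, were among the most strongly higher. The gene of the inositol oxygenase HrmE (Npun_R5328; chromosome, 6590058 to 6590954, minus strand) had 113 counts at 0 h and 45511 at 1 h, a log2 difference of 7.29 with a 95% counting interval of 7.03 to 7.57. The D-mannonate oxidoreductase gene Npun_F5334 stood at 7.45 (6.88 to 8.19), the glucuronate isomerase gene uxaC (Npun_F5333) at 6.08 (5.91 to 6.26) and the gene of the regulator HrmR (Npun_F5332) at 5.02 (4.84 to 5.21), with intervals in parentheses. In contrast, the cupin gene Npun_R5042 (chromosome, 6247168 to 6247620) was the lowest gene with an informative product, from 20356 counts to 209, at −7.95 (−8.17 to −7.77).

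Other genes among the 10 most strongly higher at 1 h, of those with an informative product, included the flavin reductase gene Npun_R0591 (chromosome, 701826 to 703562) at 7.50 (7.40 to 7.61) and the drug transporter gene Npun_R5592 at 5.92 (5.69 to 6.17). Adjacent genes annotated as parts of a nitrate ABC transporter stood at 5.71 (Npun_R2354) and 5.21 (ntrB, Npun_R2355). The group included an export locus as well, with log2 values of 5.65 for the peptidyl-prolyl isomerase gene Npun_F5889, 5.16 for the ABC exporter gene Npun_F5890 and 5.24 for the HlyD-type secretion gene Npun_F5892. Among the lowest genes at 1 h were the lanthionine synthetase gene Npun_F5047 at −6.57 (−6.66 to −6.49) and its neighbour Npun_F5048, of the HlyD type, at −6.30 (−6.48 to −6.14). The gene chlL (Npun_R4422), which encodes a subunit of the light-independent protochlorophyllide reductase of chlorophyll synthesis, stood at −4.70 (−4.75 to −4.66). The kelch-repeat gene Npun_F2730 stood at −4.47, the cupin gene Npun_F5858 at −4.46, the elongation factor G gene Npun_R5063 at −4.27, Npun_R1904 (Mo-dependent nitrogenase family) at −3.97, the NUDIX hydrolase gene Npun_F5727 at −3.85 and the protein kinase gene Npun_F5309 at −3.69.

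**Figure D1:**
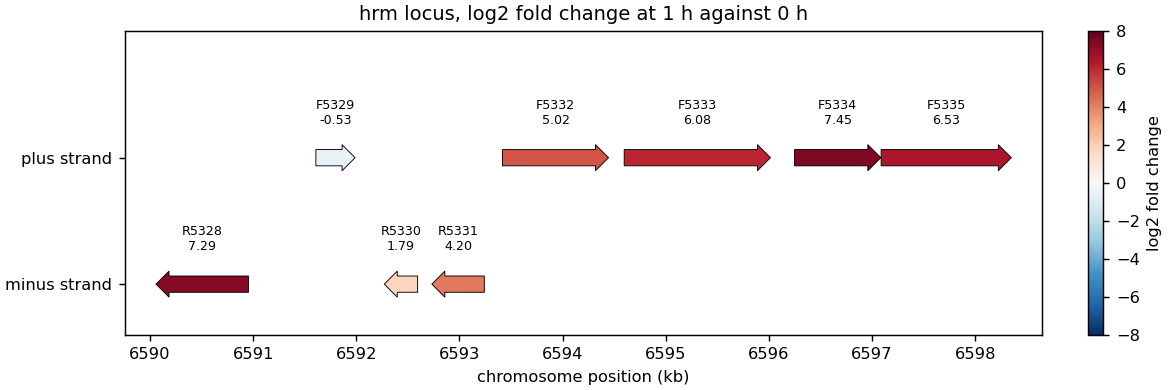
Map of the hrm locus on the chromosome (horizontal axis in kb; arrows show genes on the plus strand, upper line, and the minus strand, lower line), coloured by the log2 ratio of scaled counts at 1 h to 0 h, with 1 library per time. The value under each locus number runs from −0.53 for Npun_F5329 to 7.45 for Npun_F5334; the locus was chosen after its values were seen.

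In all, 200 of the 6169 genes above the count minimum were at least 4-fold higher at 1 h than at 0 h and 214 were at least 4-fold lower. Scaling to the total count gave 743 higher and 54 lower, and scaling to the total without psaA and psaB gave 442 and 98. Of the 28 gene lists that were scored, 5 had medians above and 4 below the central 95% of random lists matched on expression. Random lists hold few neighbouring genes, while log2 ratios of same-strand neighbours were correlated (Pearson r of 0.82 across gene pairs at 1 h), so lists of adjacent genes can fall outside more readily. Phycobilisome genes, which build the light-harvesting antenna, had a median log2 ratio of −2.15, with 12 of 23 members at least 4-fold lower and none at least 4-fold higher. The photosystem I list had a median of −2.09, with 9 of 17 members at least 4-fold lower. Photosystem II genes had a median of −0.82, which became 0.08 with total-count scaling, and 5 of 36 were at least 4-fold lower while 4 were at least 4-fold higher. Genes of translation factors and tRNA synthetases had a median of 0.87 (percentile 100 among random lists), with glyS at 1.83 and aspS at 0.89. Ribosomal protein genes had a median of 0.44 (percentile 98.5), from −1.41 for rpsF to 1.78 for rplD. Glycosyl transferase genes had a median of 0.55 and cyclic nucleotide signalling genes of 0.60, both above the random range. Gas vesicle genes, for the protein shells that give buoyancy, had a median of 0.87 (percentile 98.2), with 2 of 9 at least 2-fold higher.

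At 6 h, a question was which of the early differences were still present and which groups had joined them. The transporter gene Npun_R5592 (chromosome, 6902261 to 6903850) was the most strongly higher gene with an informative product, at 6.31 (6.08 to 6.56). The hrm genes named above were still higher than at 0 h, with 5.19 for Npun_F5334, 4.19 for uxaC, 3.76 for HrmE and 3.58 for HrmR, each below its 1 h value. Of the 8 genes of the locus, 5 were at least 4-fold higher at 6 h. Npun_F5329 and Npun_R5330 each stood at −0.17, which turned positive with total-count scaling. New among the 10 highest was, among others, the beta-helix repeat gene Npun_R5506 (chromosome, 6807487 to 6808866), with 9442 counts at 0 h and 405987 at 6 h, a log2 ratio of 4.59 (4.56 to 4.62). The stress-related genes of a CsbD family protein (Npun_R0959) and a small heat shock protein Hsp20 (Npun_F1627) were among the lowest, at −6.06 (−6.28 to −5.87) and −4.82 (−4.88 to −4.77). The phycoerythrin genes CpeB (Npun_R3807) and CpeA (Npun_R3806), for antenna pigment proteins, stood at −5.05 and −4.78.

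The flavin reductase gene Npun_R0591 stood at 5.13, Npun_F1911 (Mo-dependent nitrogenase family) at 3.97 and the psbA copy Npun_F3544 at 3.78. On the lower side, the flavodoxin gene fldA (Npun_R6154) stood at −5.06 (−5.37 to −4.79), the cupin gene Npun_R5042 at −5.06 and chlL at −4.72. Genes of a locus with amino acid adenylation domains were lower together, with −4.67 for Npun_F2183, −4.71 for Npun_F2184 and −4.79 for the nearby ATP-grasp gene Npun_F2189. In total, 157 genes were at least 4-fold higher at 6 h than at 0 h and 275 at least 4-fold lower. Total-count scaling gave 797 higher and 93 lower, and the total without psaA and psaB gave 459 and 154. Medians of 6 lists lay above the random range and those of 6 lay below it.

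Gas vesicle genes, whose median was already above the random range at 1 h, had a median of 1.96 at 6 h, with 7 of 9 at least 2-fold higher and 4 at least 4-fold higher. The hmp locus, a chemotaxis-like gene set needed for hormogonium motility, had a median of 1.59, and all 6 members were at least 2-fold higher. Genes of the ATP synthase had a median of −1.28, with 7 of 9 at least 2-fold lower, and those of tetrapyrrole and chlorophyll synthesis had −1.24, with 15 of 27 at least 2-fold lower. The medians of the phycobilisome, photosystem I and photosystem II lists were −2.70, −2.58 and −1.30. Transposase genes had a median of −0.40, which was 0.53 with total-count scaling and 0.17 with the total without psaA and psaB and lay below the random range with each of these scalings.

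The comparisons of 12 h and 18 h with 0 h cover the later course of development. Lists of motility and surface polysaccharide genes had medians above 0, and those of light harvesting genes had medians below 0. At 18 h, hpsA (Npun_F0066; chromosome, 103560 to 108260), in a locus for hormogonium polysaccharide, stood at 3.05 (3.03 to 3.06), from 39973 counts at 0 h to 397758. The pilus retraction motor gene PilT (Npun_R0117; chromosome, 164328 to 165455) stood at 2.59 (2.57 to 2.62), hmpF (Npun_R5959) at 2.30 (2.28 to 2.33) and the chemoreceptor gene Npun_F2164 of the phototaxis (ptx) locus at 2.60 (2.58 to 2.62). CpeB stood at −5.82 (−5.84 to −5.79), cpcA (phycocyanin, Npun_F5290) at −4.53 (−4.54 to −4.51) and psaA at −3.76 (−3.76 to −3.75).

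At 12 h, the 10 highest named genes included Npun_R5592 at 7.20, Npun_R0591 at 4.89, the peptidoglycan-binding gene Npun_R1782 at 4.17, the HlyD-type gene Npun_F3670 at 3.87 and the plasmid gene Npun_BF118 (DnaB domain; pNPUN02) at 3.66. At 18 h, Npun_R5592 reached 7.87 (7.64 to 8.12). A hemolysin-type calcium-binding gene, Npun_R2919 (chromosome, 3608303 to 3611848), had 1583 counts at 0 h and 204241 at 18 h, with log2 ratios of −0.38 at 1 h, 0.90 at 6 h, 3.53 at 12 h and 6.75 at 18 h. Further genes among the 10 highest at 18 h included Npun_R1782 (5.31), the Rieske-type gene Npun_F6506 (4.66), Npun_F3670 (4.66), the potassium pump gene kdpB (4.20) and the efflux gene Npun_F4015 (4.07). The transferase gene Npun_F3048, at 4.11 (3.15 to 5.57), and the esterase gene Npun_F4607, at 4.01 (3.18 to 5.17), had only 7 and 10 counts at 0 h and wide intervals.

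Among genes with an informative product, the lowest at 18 h, after CpeB and CpeA (−5.73), were Npun_F2189 (−5.68), the cupin gene Npun_F5858 (−5.42), Npun_F2184 (−5.28), chlL (−5.16), the peptidoglycan-binding gene Npun_R4589 (−5.12), Npun_F2183 (−4.92), fldA (−4.90) and psbO (−4.77), which encodes the manganese-stabilizing protein of photosystem II. At 12 h, the 10 lowest such genes were CpeB (−5.94), CpeA (−5.91), chlL (−5.46), Npun_F2189 (−5.36), fldA (−5.35), Npun_F5858 (−5.13), Npun_F2184 (−5.11), Npun_R4589 (−5.05), Npun_F2183 (−4.93) and the alcohol dehydrogenase gene Npun_F2186 (−4.80). At 12 h, 244 genes were at least 4-fold higher and 336 at least 4-fold lower, against 854 and 172 with total-count scaling and 487 and 252 with the total without psaA and psaB. At 18 h, 372 were higher and 393 lower, against 736 and 247 with total-count scaling and 401 and 377 with the total without psaA and psaB.

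The motility lists differed in when their medians left the random range. That range differs between lists, and at 18 h its upper edge was 1.99 for the 6 pilus genes and 0.65 for the 31 chemotaxis genes. This measure therefore does not order the lists in time. The type IV pilus list had medians of 0.24, 0.94, 2.07 and 1.94 at 1, 6, 12 and 18 h. All 6 of its genes were at least 2-fold higher at 12 h and 18 h, and its median lay above the random range at 12 h (percentile 99.5) and within it at 18 h (percentile 97.0). Its members included pilM (2.07 at 18 h), PilO (1.80), PilA (1.78) and Npun_F0676 (1.80). In the hps locus the medians were 0.34, 0.56, 1.59 and 1.90, with 5 of 11 genes at least 4-fold higher at 18 h, among them hpsB (2.17), hpsC (2.37) and the hpsE copy Npun_F0071 (2.26). The transposase gene inside that locus, Npun_F0076, stood at −0.53.

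Chemotaxis genes had a median of −0.50 at 1 h, which was 0.39 with total-count scaling and 0.07 with the total without psaA and psaB and lay below the random range with each of these scalings (percentile 1.46 with trimmed-mean scaling). Their medians were 0.35 at 6 h, 1.51 at 12 h and 1.55 at 18 h, with 20 of 31 at least 2-fold higher and 2 at least 2-fold lower at 18 h. The ptx locus, which holds phototaxis genes, followed a like course, from −0.62 at 1 h, where total-count scaling gave 0.28, to 0.43, 1.69 and 2.01. All 8 of its genes were at least 2-fold higher at 18 h, from the receptor gene Npun_F2167 (1.56) to Npun_F2164. In the hmp locus, medians were 0.71, 1.59, 1.85 and 1.92, and the CheA-type kinase gene Npun_F5964 reached 2.26. Several chemotaxis genes belong to the hmp or ptx locus too, so these lists are not independent. Gas vesicle genes had medians of 2.00 at 12 h and 1.27 at 18 h, and between these times 5 of 9 were at least 2-fold lower. The structural gene gvpA stood at −0.64, 0.22, 1.44 and 1.70, the 1 h value turning positive with total-count scaling, and gvpN at 0.74, 2.05, 2.00 and 0.69.

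**Figure D2:**
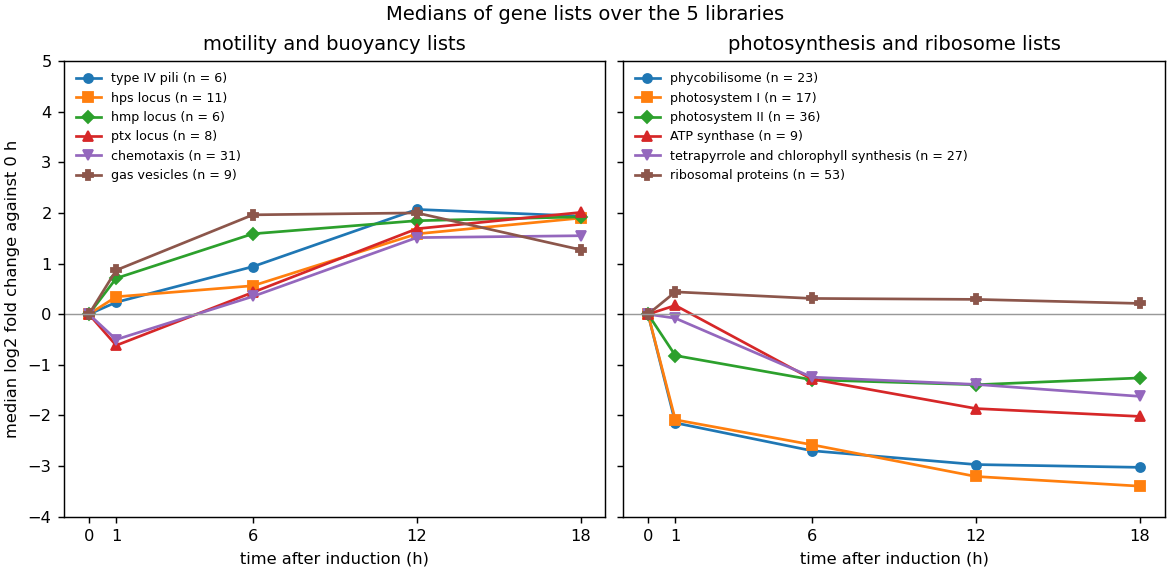
Median log2 ratio of scaled counts to 0 h (vertical axis) of gene lists against time after induction in hours (horizontal axis), with 1 library per time, motility and buoyancy lists on the left and photosynthesis, pigment and ribosome lists on the right; n is the number of genes. The phycobilisome and photosystem I medians reach −3.02 and −3.40 at 18 h; with total-count scaling the 1 h medians of chemotaxis, the ptx locus, photosystem II and tetrapyrrole synthesis turn positive.

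The phycobilisome, photosystem I and photosystem II lists were below the random range at every time, also with total-count scaling, where the photosystem II median at 1 h turned positive. At 18 h, 17 of 23 phycobilisome genes were at least 4-fold lower (median −3.02), including the linker genes ApcE (−2.47) and CpcC2 (−3.02). The gene of NblA (Npun_R3808), which acts in phycobilisome breakdown, was higher, at 1.39 (0.96 to 1.86). Of the photosystem I genes, 12 of 17 were at least 4-fold lower (median −3.40), with psaB at −3.68, PsaD at −3.40 and the psaK copy Npun_R1705, whose product is given as hypothetical, at −5.06, while the assembly protein gene Ycf3 stood at −0.39, which became 0.11 with total-count scaling. Photosystem II had a median of −1.26, with psbB at −1.19 and psbD at −1.17. ATP synthase genes had medians of −1.86 at 12 h and −2.02 at 18 h, with atpA at −1.74 and Npun_F4864, for the gamma subunit, at −2.02. Tetrapyrrole and chlorophyll synthesis genes had a median of −1.62 at 18 h, with 20 of 27 at least 2-fold lower and acsF (Npun_F1653) at 2.40.

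The psbA copies, which encode the D1 reaction centre protein, stood apart from each other. At 1 h, Npun_R2273, Npun_F3544 and Npun_R5188 had log2 ratios of 4.50, 4.70 and 4.32, while Npun_R5455 and Npun_F1022 had −2.82 and −2.63. At 18 h the 5 values were 4.00, 3.88, 3.74, −0.20 and −0.24, of which the last pair became 0.30 and 0.27 with total-count scaling. Copies of psbA are often near-identical in sequence and could share reads, so their separate values are uncertain. Among carbon fixation genes, the median was −0.59 at 18 h and within the random range at all 4 times, with rbcL at −1.07; its medians of −0.35 at 6 h and −0.60 at 12 h turned positive with total-count scaling.

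Lists of signalling genes had medians above 0, with members in both directions. Genes of histidine kinases and response regulators had medians of 0.28, 0.49 and 0.57 at 6, 12 and 18 h, above the random range, and 33 of 197 were at least 4-fold higher and 12 at least 4-fold lower at 18 h, the highest being the plasmid-borne kinase gene Npun_AR131 (3.06). Cyclic nucleotide genes had medians of 0.85 and 0.82 at 12 h and 18 h, with the diguanylate cyclase gene Npun_R5282 at 2.35. Of these 42 genes, however, 4 were at least 4-fold higher and 6 at least 4-fold lower at 18 h, and their mean was 0.36. Peptidoglycan and rod shape genes had medians of 0.75 and 0.65, with murC at 1.86 and the extremes Npun_R1782 and Npun_R4589 given above. Of the 13 sigma factor genes, which direct RNA polymerase to promoters, sigC (Npun_F0996; chromosome, 1178470 to 1179720) was higher from 1 h on, at 2.28, 1.66, 2.03 and 2.25. Npun_R1337 and Npun_F4811, both named SigF in the annotation used here, reached 1.82 and 1.86 at 18 h. The sigma factor gene Npun_R4091 was lowest at 6 h (−2.35). Npun_R1771 stood at 2.35 (1.56 to 3.38) from 13 counts at 0 h, and rpoD lay between 0.19 and 0.52 at all 4 times. The sigma factor list as a whole was within the random range, with a median of 0.85 at 18 h.

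**Figure D3:**
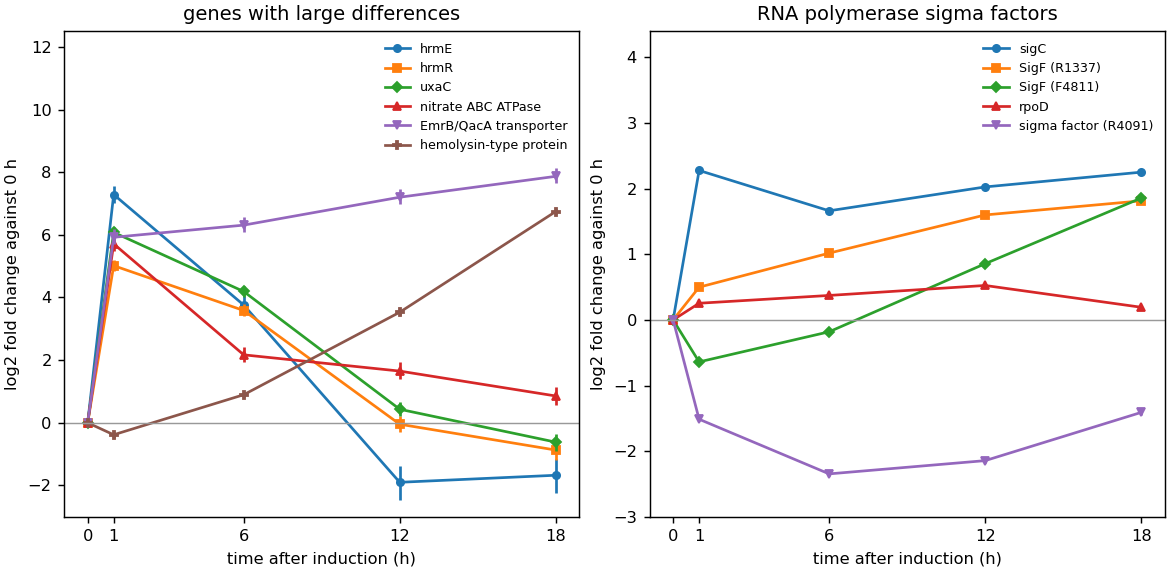
Log2 ratio of scaled counts to 0 h (vertical axis) against time after induction in hours (horizontal axis) for named genes (left) and sigma factor genes (right), with 1 library per time; vertical bars are 95% counting intervals, often smaller than the symbols. HrmE peaks at 7.29 at 1 h, the EmrB/QacA transporter Npun_R5592 reaches 7.87 at 18 h and sigC stays between 1.66 and 2.28; the 1 h and 6 h values of the SigF gene Npun_F4811, −0.64 and −0.18, turn positive with total-count scaling.

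Lists for heterocysts, the nitrogen-fixing cells that a culture could hold, were within the random range at all 4 times. The heterocyst list had a median of 0.37 and the nitrogen fixation list of −0.05 at 18 h, which total-count scaling turned to 0.45. The regulator genes hetR and ntcA stood at 0.06 and 0.39, and the devC copies Npun_R2169 and Npun_F1298 at 3.81 and −1.62. Cell division and DNA replication genes had a median of 0.11, with ftsZ at 1.73 at 6 h and 0.94 at 18 h and ftsE at 2.38. Chaperone genes went both ways, with the dnaK copies Npun_F0567 and Npun_F0122 at −2.49 and 2.23 and the groEL copy Npun_R0829 at −2.51. The NDH-1 list had a median of −0.48 at 18 h, which was 0.03 with total-count scaling and lay below the random range with both, while at 1 h its members Npun_F3686 and Npun_F3688 stood at 2.56 and 2.83.

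Nitrogen assimilation genes had medians of −0.15, 0.38, 0.37 and 0.42 at 1, 6, 12 and 18 h, the 1 h value becoming 0.75 with total-count scaling. Genes of sugar catabolism and glycogen had 0.13, 0.09, 0.21 and −0.08, the 18 h value becoming 0.43. Secondary metabolism genes had −0.17, −0.05, −0.08 and −0.24, and chaperone genes −0.32, −0.09, −0.07 and −0.01, all of them positive with total-count scaling. These 4 lists were within the random range at all 4 times. Transposase genes, whose similar copies make single values uncertain, had medians of −0.19 at 12 h and −0.19 at 18 h, which were 0.57 and 0.31 with total-count scaling and lay below the random range with both scalings. Glycosyl transferase genes stood at 0.53 at 18 h, above the random range, with 13 of 97 at least 4-fold higher and 1 at least 4-fold lower. The circadian clock list held only kaiB and kaiC, too few to be scored, and had a median of 0.79 at 1 h and −0.36 at 18 h, the latter 0.15 with total-count scaling.

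Steps between consecutive times after 1 h gave fewer genes than comparisons with 0 h. From 1 h to 6 h, 54 genes were at least 4-fold higher and 79 at least 4-fold lower. From 6 h to 12 h, 7 were higher and 8 lower, and 6 of the 8 lower genes were in the hrm locus, led by HrmE at −5.66. Upper-quartile scaling gave 1 higher and 10 lower for that step, total-count scaling gave 1 and 11, and the total without psaA and psaB gave 1 and 12. From 12 h to 18 h, the gene Npun_R2919 was higher (3.22), and 4 genes were at least 4-fold lower, including Npun_R2402 (−2.59), the histidine decarboxylase gene Npun_F1479 (−2.08) and the Fis-type regulator gene Npun_R6332 (just past 4-fold). Npun_R2402, Npun_F1479 and Npun_R6332 were named after their values were seen, and for none of the 4 lower genes did the whole counting interval lie beyond 4-fold.

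**Figure D4:**
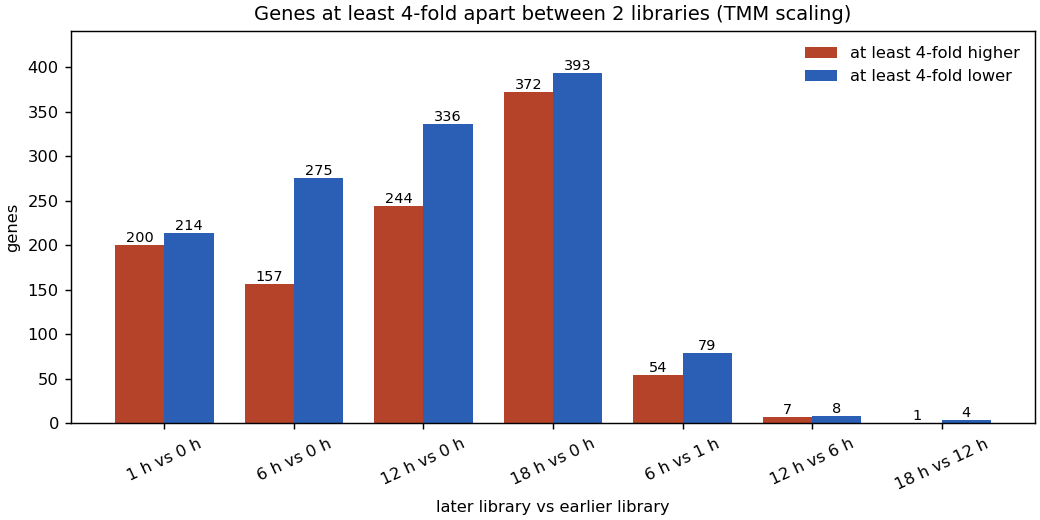
Numbers of genes (vertical axis) at least 4-fold higher or lower in the later of 2 libraries (horizontal axis, each pair of times), of 6169 genes, with trimmed-mean scaling. The counts against 0 h run from 200 higher and 214 lower at 1 h to 372 and 393 at 18 h; total-count scaling gives 743 and 54 at 1 h and 736 and 247 at 18 h.

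Of 1320 genes with at least a 4-fold range over the 5 libraries, 467 had their highest scaled value at 0 h, 262 at 1 h, 101 at 6 h, 92 at 12 h and 398 at 18 h. With total-count scaling a different and larger set of genes had such a range, and the numbers were 218, 664, 424, 302 and 436. At all of 1, 6, 12 and 18 h, 33 genes were at least 4-fold higher and 121 at least 4-fold lower than at 0 h. Of the 200 genes higher at 1 h, 58 were also at least 4-fold higher at 18 h, and 91 were within 2-fold of 0 h by then. The 12 h and 18 h lists shared 166 higher and 303 lower genes, where independent lists would share 14.7 and 21.4 and simulated libraries that differed by counting noise only shared 0. For 1 h and 18 h the shared numbers were 58 higher and 128 lower, against 12.1 and 13.6 for independent lists. The simulated 0 follows from the 4-fold threshold and holds no variation between cultures. Part of the excess may come from the 0 h library that all of these comparisons share.

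The authors' deposited table gives a q-value for each pair of libraries, from a test that is not named and that compares those libraries, not the conditions. At a q-value below 0.05, the authors' deposited table holds 48 genes for 1 h against 0 h, 70 for 6 h, 76 for 12 h and 83 for 18 h. All of these genes in the authors' deposited table were among those at least 4-fold apart here, which numbered 414, 432, 580 and 765. For these genes in the authors' deposited table, directions were taken from the log2 ratios computed here. By these ratios, 26 were higher and 22 lower at 1 h, and 28 were higher and 55 lower at 18 h.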

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

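The tests on antisense RNAs were fixed before their results were seen, except those by family, which were added afterwards, and the genes with opposite directions were found from their values. Differences between times were not tested, since each time has 1 library.

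Predicted RNAs outside the genes compared here carried differences from 0 h. Of 301 above the count minimum, 13 were at least 4-fold higher at 1 h, 11 at 6 h, 20 at 12 h and 33 at 18 h, and 45, 45, 43 and 40 were at least 4-fold lower. A predicted RNA at 704390 to 705963 on the minus strand of the chromosome had 434 counts at 0 h and 226355 at 1 h, a log2 ratio of 7.67. It lies 163 bp from the hypothetical gene Npun_R0592, at 8.02 at 1 h, and 15 bp from the transposase gene Npun_R0594, at 1.43. Another at 3297069 to 3297346 had 567746 counts at 0 h and 19394 at 1 h, at −6.23. One beside Npun_R2919, at 3608245 to 3608302, stood at 6.83 (5.85 to 8.42) at 18 h, from only 6 counts at 0 h. A short RNA beside the hrm locus, at 6589502 to 6589742, stood at 5.11 at 1 h and adjoins the gene Npun_R5327, at 3.86. Another within the locus, at 6594466 to 6594596, stood at 5.81 and adjoins uxaC. Whether these RNAs are separate from the transcripts of the adjoining genes was not tested. The predicted RNAs named here were chosen after their values were seen.

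Chemotaxis genes stood out because their direction differed between times. With trimmed-mean scaling their median was −0.50 at 1 h and 1.55 at 18 h. The 1 h median became 0.39 with total-count scaling, so the change of direction depends on the scaling. Its place below the random range does not decide the direction, because random lists shift with the scaling too. The locus of a CheA-type kinase and a receptor with a phytochrome domain held the clearest single cases. Npun_R6010 stood at −2.26 at 1 h and 2.38 at 18 h, the hypothetical gene Npun_R6011 at −2.32 and 3.13, and Npun_R6012 at −2.07 and 2.73. Npun_F1405, a hypothetical gene among phage tail genes, stood at −2.09 at 1 h and 2.27 at 6 h. Npun_R2402 stood at 2.60 at 1 h and −3.70 at 18 h, but its 18 h value rests on 3 counts (interval −6.34 to −2.35).

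Some predicted antisense RNAs differed between 0 h and 18 h, and in 7 of 95 pairs with a gene the antisense RNA was at least 4-fold apart. Reads of the gene on the other strand, counted as antisense, could account for this. Such reads would make the log2 ratios of an antisense RNA and its gene alike. Across 95 pairs from 75 antisense RNAs, Pearson r at 18 h was −0.028 (95% bootstrap interval −0.27 to 0.25). However, 56 of the 95 pairs belong to 4 families of near-identical ratios, mostly transposase elements, and 33 to the largest, so these pairs are not independent and that interval is uncertain. With 1 mean value for each of 38 families, r was −0.25 (−0.58 to 0.10) and the median absolute difference was 1.55, which argues against such reads as the whole cause. By family, r was −0.06, −0.40 and −0.28 at 1, 6 and 12 h, with an interval below 0 at 6 h only (−0.63 to −0.10). Whether antisense RNA lowers its gene stays open, because the interval at 18 h has values on both sides of 0.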

How the results depend on the processing

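Predicted RNAs kept, thinned depth, the 1 h reference, total counts without psaA and psaB, antisense RNAs by family and the added lists were chosen after seeing the data; the others were planned. No paired analysis was possible because each group has 1 library. Over all alternatives, 280 counts of genes or lists stayed within 1.5 times and 60 did not. Of the list medians, 995 moved by no more than the distance from the middle of the list's random range to its edge, 116 by more, and 9 changed sign after being outside the random range. Of the values of named genes, 3851 stayed within their counting interval and 2001 did not, with none at least 4-fold changing sign. With median-of-ratios scaling all 27 counts stayed within 1.5 times, while with total-count scaling 14 of 27 did not. The counts of lists among them do not change with the scaling, because random lists shift alike.

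Total-count scaling gave 743 higher and 54 lower genes at 1 h, 797 and 93 at 6 h, 854 and 172 at 12 h and 736 and 247 at 18 h. From 6 h to 12 h it gave 1 higher gene, and from 12 h to 18 h 7 lower. The peak times 0, 1, 6 and 12 h then held 218, 664, 424 and 302 genes of a larger set. All 28 lists kept their place against random lists at all 4 times, since random lists shift alike, with 5 above and 4 below at 1 h, 6 and 6 at 6 h, 10 and 6 at 12 h and 9 and 7 at 18 h. Of the medians outside the random range, those of chemotaxis (0.39) and photosystem II (0.084) at 1 h changed sign with the shift. So did those of the NDH-1 complex (0.028) at 18 h and transposases (0.53, 0.57 and 0.31 at 6, 12 and 18 h). Several medians within the random range changed sign too, such as that of the ptx locus at 1 h (0.28). Without psaA and psaB in the total, there were 442 higher and 98 lower genes at 1 h, 459 and 154 at 6 h and 487 higher at 12 h, while 401 and 377 at 18 h were close to 372 and 393 with trimmed-mean scaling. From 6 h to 12 h there was 1 higher gene, from 12 h to 18 h 7 lower, and peaks at 1, 6 and 12 h numbered 580, 294 and 174. Of the medians outside the random range, that of chemotaxis at 1 h became 0.067, and those of transposases became 0.17 at 6 h and 0.13 at 12 h. By construction, total-count scaling keeps the large psaA and psaB share at 0 h in the total.

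At 2-fold, the counts were larger because the threshold is lower: 883 higher and 913 lower at 1 h, 885 and 979 at 6 h, 1173 and 1096 at 12 h and 1226 and 1222 at 18 h. The steps then gave 352 and 495, 272 and 127, and 154 and 160, and the peak times 1350, 914, 480, 313 and 1081 genes. Against the 1 h library, 54 genes were higher and 79 lower at 6 h, 116 and 144 at 12 h and 232 lower at 18 h, with peaks of 27 at 12 h and 261 at 18 h. This follows in part from leaving out the 0 h library.

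The steps with few genes moved most. From 6 h to 12 h, 1 gene was higher with upper-quartile scaling, 3 with their whole counting interval beyond 4-fold, and 11 higher and 23 lower with no count minimum. From 12 h to 18 h, no count minimum gave 10 higher and 35 lower, predicted RNAs kept gave 3 higher, and lower genes numbered 2 with a pseudocount of 10, 2 with a minimum of 200 counts and 0 beyond the interval. The cause was not tested beyond what these settings change by construction.

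With counts thinned to the shallowest library, 190 of the 200 higher and 205 of the 214 lower genes at 1 h were shared, and 367 of the 372 and 378 of the 393 at 18 h. With their whole counting interval beyond 4-fold, 146 genes were higher and 193 lower at 1 h, and 291 and 331 at 18 h.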

Other observations

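The test of photosystem I under other scalings was chosen after its result was seen, and the other tests were not; the loci described here were chosen after their values were seen. Several groups of adjacent genes, some with members in the fixed lists, were higher or lower together. They were picked as runs of genes that were all at least 4-fold apart in the same direction at the times given. Their shared direction and the size of their medians therefore follow in part from that choice. The 11 genes from Npun_R0680 to Npun_R0690 (chromosome, 810743 to 821073), which include pseB, pseC, pseG and pseI of nonulosonic acid synthesis, had a median log2 ratio to 0 h of 2.52 at 1 h. The 6 genes from Npun_R4846 to Npun_R4851, annotated as glycosyl transferases and polysaccharide synthesis proteins, had a median of 3.42 at 1 h and 2.86 at 6 h. The potassium pump genes Npun_F0719 to Npun_F0721 (kdpB, subunit F and kdpC) had a median of 2.91 at 1 h and 3.22 at 18 h. The 5 genes from Npun_F3686 to Npun_F3690, with NDH-1 subunits, a carbonic anhydrase and a CO2 hydration protein, had a median of 2.82 at 1 h. The 7 genes from Npun_F2137 to Npun_F2143, with devC copies of an exporter, had a median of 2.47 at 12 h. The genes Npun_F2181 to Npun_F2187 (2667205 to 2706307), with amino acid adenylation domains, had medians of −4.30 at 6 h, −4.80 at 12 h and −4.52 at 18 h.

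Phage tail-like genes followed another course. The 13 genes from Npun_F1401 to Npun_F1413, with sheath, tail and GPW/gp25 proteins, had medians of −1.79 at 1 h, 2.25 at 6 h, 1.29 at 12 h and 0.72 at 18 h, and 13 of 13 were at least 4-fold higher at 6 h than at 1 h. Total-count scaling left the 1 h median negative, at −0.89. Of the plasmids, pNPUN03 had a median of −0.65 over 58 genes at 18 h, with 12 at least 4-fold lower and 0 higher, and total-count scaling left it at −0.14. At 1 h its median was −0.57, which became 0.33 with total-count scaling. The plasmid pNPUN01 had medians of 0.30, 0.18, 0.27 and 0.24 at 1, 6, 12 and 18 h, above random lists.

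The pil loci added after values were seen (Npun_R0116 to Npun_R0118 and Npun_F5005 to Npun_F5008, 7 genes) had medians of 0.63, 1.43, 2.26 and 2.59 at 1, 6, 12 and 18 h. The 8 genes of the hrm locus had 5.55, 3.67, 0.19 and −0.66.

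Photosystem I genes were lower at 18 h than at 0 h, with a median log2 ratio of −3.40 over 17 genes. Library composition and scaling may produce such a pattern. With psaA and psaB left out, the highest median over 5 scalings was −2.73 (spread 0.27, 15 genes), so the choice among these scalings does not account for it. The spreads in this paragraph come from the interquartile range, scaled down by the square root of the number of genes as if these were independent. Genes of an operon are not, and the values of the 17 genes had quartiles of −3.76 and −1.78. Total-count scaling raised the median of all genes by only 0.50 at 18 h, so these scalings could not have removed the difference. An effect of composition common to all of them was not tested. Coding length is not the whole cause, since subtracting the running median against coding length left −3.05 (spread 0.24). Transfer to fresh medium without regard to the inducing factor stays open, because 0 libraries of washed filaments without the factor were analysed here. Development of hormogonia, which the time course follows, stays open too and cannot be told apart from that transfer.

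Differences of at least 4-fold between single libraries could come from independent noise per gene. Such noise would not be shared by genes that adjoin on the same strand. Across gene pairs, Pearson r of the log2 ratios was higher for same-strand neighbours under 100 bp apart than for opposite-strand neighbours by 0.71 (0.66 to 0.77) at 1 h and 0.66 (0.61 to 0.71) at 18 h, where independent simulated counts gave 0.049 at 1 h. Each gene at least 4-fold higher at 1 h was paired with every such neighbour that it had. In 136 of these 148 pairings (91.9%) the neighbour was at least 2-fold higher too, against 14.3% of all genes. For genes at least 4-fold lower at 1 h, the neighbour was at least 2-fold lower in 74 of 80 pairings (92.5%), against 14.8% of all genes. For genes with such a neighbour, this argues against independent noise as the source of these differences. Genes without one were not covered. The values do not argue against a difference between cultures that moves whole operons, which stays open without replicates.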
